A study of Homo sapiens with 10 samples.

How the data were processed

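The data came from 10 Affymetrix HG_U95A oligonucleotide arrays of total RNA from MDA-MB-468, a human breast adenocarcinoma line. Per the labels, 2 stable clones were grown under selection with 400 µg/ml of G418. K3 carries a Smad4 construct and is called the Smad4-positive clone here. A26 carries a β-galactosidase construct and is called the Smad4-negative clone. Each clone gave 1 array without treatment and 1 array each after 20 min, 1 h, 4 h and 12 h of TGF-β at 10 ng/ml. All 10 arrays were used, and the table held 0 columns of other samples. Only 1 clone stood for each Smad4 state, so clone identity and Smad4 state could not be separated by any test.

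The authors deposited 1 linear signal value per probe set and array, for 12626 probe sets. The algorithm and the software that made the signal values are not given in the sources used here, and neither is a detection call. The values showed a common scaling, because the mean signal after trimming 2% at each end was 1000.5 to 1000.6 on every array. Signals ranged from 0.7 to 81629.2. The deposited signal was therefore used without further scaling, which the plan allowed where these means lay within 1.25-fold of each other. Per the file headers, all arrays were of the same type. By the dates of hybridization and scan in the same headers, the untreated and 20 min arrays of both clones formed 1 group, called run A. The 4 h and 12 h arrays of both clones formed another, called run B. A run here means shared dates only. For the 2 arrays of 1 h the headers gave no such date. They also logged a fluidics error for the Smad4-positive 20 min array. Early and late times were thus confounded with the run, while both clones were present in each run.

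Of the 12626 probe sets, 67 were controls and 12559 were not. A deposited table paired 10943 probe sets with 1 gene symbol and 546 with several symbols, and 1070 non-control probe sets had none. Only probe sets with 1 symbol were named, and they represented 8225 genes. By Entrez identifier, 10949 probe sets matched the RefSeq table of assembly GRCh38.p14, and 0 symbols needed updating. That assembly was used only to find which genes neighbour each other.

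Signals below the 20th percentile of all values pooled, which was 59.5, were set to that floor and all values were taken to log2. Probe sets above the pooled median of 282.6 on at least 2 arrays were tested, which gave 7416 probe sets and 5405 genes. A gene with several probe sets was represented by the one with the highest mean. Fold changes against a level at the floor understate the true ratio, and are written as lower bounds where every array of a clone was at the floor.

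Every model was fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend. Benjamini-Hochberg adjustment ran over the 7416 probe sets, with a threshold of 0.05. The clone difference, Smad4-positive minus Smad4-negative, came from an additive model of clone and time as a factor of 5 levels. Time paired the arrays of both clones, and 4 residual degrees of freedom remained. Contrasts of each time with the untreated arrays over both clones came from the same model. Time trends were slopes on log2(1 + hours), 1 per clone, with 6 residual degrees of freedom shared by the clones, and their difference was tested as well. A slope is thus a log2 change per doubling of (1 + hours). It follows steady change and misses short peaks. Differences within a clone at a single time set 1 array against 1 and carry no test. The p-values measure only the spread between these arrays, since nothing in the sources says that the arrays came from separate cultures. The number of arrays limits the precision.

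The 26 gene lists were written before the data were examined, as were the comparisons, the alternatives called planned and the rule for naming genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 24 lists with at least 5 genes tested. Camera with an estimated correlation was an alternative. The lists covered TGF-β/Smad target genes, immediate early genes, serpins, pericellular proteases and inhibitors, extracellular matrix, integrins, epithelial adhesion and keratins, mesenchymal markers, cell cycle, cell-cycle inhibitors and p53 targets, interferon response, MHC class II, NF-kB targets and chemokines, EGFR family, TGF-β superfamily, S100 and calcium binding, heat shock and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, apoptosis, fibroblast, leukocyte and endothelial markers, ribosomal proteins, proteasome and oxidative phosphorylation. For single times, the median of a list was placed among 10000 random lists of the same size matched on expression, as a description of those arrays.

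Genes were named by this rule. SMAD4 was always named. SMAD7, SKIL, JUNB, ID1, ID2, ID3, CDKN1A, MYC, TGFBI, KLF10, FOS, EGR1 and SERPINB5 were named beforehand for the TGF-β comparisons, where the report gives their slopes and 4 h contrasts and some of their values at single times, and 1 further gene of that rule is not reported here. For the clone difference the rule took the 8 most higher and 8 most lower genes past the threshold with the same sign at all 5 times, and up to 4 members of each list by adjusted p. For each slope and for their difference it took 6 genes by moderated t in each direction, and up to 3 members of each list past the threshold. Time contrasts gave 5 genes in each direction, and single times 4 genes in each direction with a neighbouring time of the same direction, few of which the report gives. Serpins past the threshold in any comparison were all named. A gene named outside this rule is said to have been chosen after its values were seen.

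The clone test, the slopes, their difference and the 4 h contrast were tested on simulated data, with 100 probe sets changed 2-fold and 100 changed 4-fold among 7416. The clone test recovered 57% of the 2-fold and 84% of the 4-fold changes. For the slope of the Smad4-positive clone the shares were 19% and 62%, and for the slope of the Smad4-negative clone 10% and 51%. The difference of slopes recovered 2% and 26%, and the contrast of 4 h with untreated 23% and 65%. The simulated noise was independent between arrays and had the spread left by the additive model of clone and time. It held no changes shared by both clones at a time, such as early peaks or steps between runs. The shares for the slopes and their difference may therefore be too high for these data.

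The alternatives changed the normalization, the floor, the filter, the variance prior, the array run as a block, the scale of time, the arrays left out, the list test and the summary of probe sets per gene. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probe sets without a single symbol were kept in the tests and left out of the lists.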

Results

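Expression was measured in MDA-MB-468, a breast adenocarcinoma line known to lack a working SMAD4 gene. SMAD4 is the partner that the TGF-β-activated Smad proteins need to regulate most of their target genes. A Smad4-positive clone and a Smad4-negative clone were each profiled on 5 arrays, at 0, 20 min, 1 h, 4 h and 12 h of TGF-β, with 1 array per clone and time and no replicates. The median signal per array lay between 247.8 and 321.5, and pairs of arrays correlated at 0.912 to 0.965 across probe sets. The ratio of the 3' to the 5' ACTB control probe sets, a sign of RNA integrity, was 1.04 to 2.63 and was highest on the Smad4-positive untreated array. The Smad4-positive 1 h array had the lowest median correlation with the others, 0.917.

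SMAD4 itself was read by 3 probe sets, and none rose above the pooled median signal on any array. The highest signals of these 3 probe sets were 136.6, 35.8 and 86.7. They were below the floor of 59.5 on 9, 10 and 8 of the 10 arrays. The highest value of all came from the Smad4-negative untreated array. Whether the probes match the part of SMAD4 carried by the construct is not given in the sources used here. These probe sets therefore did not check the labels, and the Smad4 states below are as labelled.

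The first comparison asked which genes differed between the Smad4-positive and the Smad4-negative clone over the whole time course. Among target genes of TGF-β/Smad signalling and serpins, a family of protease inhibitors, more were higher than lower in the Smad4-positive clone (12 and 1 of 28, and 7 and 1 of 13), and among genes of the cell cycle more were lower than higher (25 and 2 of 58). The 3 lists passed limma's camera, but each had an adjusted p = 0.257 with an estimated correlation. ID1, an inhibitor of differentiation factors and a classic Smad target, had a mean signal of 39775 against 2090 (log2 difference 4.25, SE 0.18, limma adjusted p = 7.52e-08, 5 arrays per clone). The matrix genes FN1, which encodes fibronectin, and TGFBI, which encodes a secreted TGF-β-induced protein, were higher by 3.93 and 3.68 log2 units. CLDN10, which encodes a tight junction claudin, went the other way, from 14712 in the Smad4-negative clone to 68.5 (log2 difference -7.75, SE 0.17, limma adjusted p = 2.09e-10). In all, 1165 of 7416 probe sets passed the threshold, 564 higher and 601 lower in the Smad4-positive clone.

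Among the other most different genes, MAGEA10, a cancer-testis antigen, was at the floor on all 5 Smad4-negative arrays and was at least 17.5-fold higher in the Smad4-positive clone. HHLA1 was higher by 3.54 log2 units, SERPINB7 by 3.12, CGA, the shared subunit of glycoprotein hormones, by 3.10, and the scaffold gene AHNAK2 by 2.97. On the lower side, SOSTDC1, a secreted antagonist of BMP and Wnt signals, differed by -3.52 and the detoxifying enzyme GSTP1 by -3.35. The chemokine CXCL1 differed by -3.27, the protocadherin PCDH8 by -3.11 and the RNA-binding IGF2BP3 by -2.95. LAMA4, a laminin chain, differed by -2.87 and the secreted phospholipase PLA2G2A by -2.81. The signals of CXCL1, LAMA4 and PLA2G2A were at the floor on 3, 4 and 3 of the Smad4-positive arrays, and CLDN10 on 2 of them, and those of CGA, AHNAK2 and TGFBI on 3, 2 and 1 of the Smad4-negative arrays, so that these differences are understated.

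Of 28 measured TGF-β/Smad target genes, 12 were higher and 1 was lower in the Smad4-positive clone, and 15 passed when adjusted over the list alone. The list as a whole was higher (limma camera adjusted p = 1.73e-05), with an adjusted p = 0.257 with an estimated correlation. Besides ID1 and TGFBI, ID3 was higher by 2.64 log2 units and CDKN1A, an inhibitor of cyclin-dependent kinases, by 1.60. Higher values were also found for SMAD7, the inhibitory Smad that feeds back on the pathway, at 1.58, for the repressor KLF10 at 1.57 and for JUNB at 0.95. SKIL and ID2 were too dim to be tested. Of 21 ligands, receptors and modulators of the TGF-β superfamily, 7 were higher and 2 lower (camera adjusted p = 0.0861), with 10 past when adjusted over the list alone. TGFB1, the ligand, was higher by 1.247 (1 other probe set of it had the opposite sign), BMP1, a procollagen protease, by 1.53, and FSTL3, a secreted activin binder, by 0.93. Without the 20 min arrays this group had 5 higher and 0 lower members. Of 21 immediate early genes, 5 were higher and 1 lower (camera adjusted p = 0.172), with 6 past when adjusted over the list alone, and 3 higher and 0 lower without the 20 min arrays. IER3, JUND and FOSL1 were higher by 0.86, 0.72 and 0.80.

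Of 13 measured serpins, 7 were higher and 1 was lower, and 9 passed when adjusted over the list alone (limma camera adjusted p = 0.00108, adjusted p = 0.257 with an estimated correlation). Next to SERPINB7, SERPINB3 was higher by 2.41 log2 units, SERPINB5, the gene of maspin, by 2.39, and SERPINA3, the gene of antichymotrypsin, by 2.17. Smaller differences were found for SERPINB8 (1.49), SERPINB1 (1.248) and SERPINE2 (0.68). SERPINH1, a collagen chaperone of this family that inhibits no protease, was the lower member at -0.52, with 1 other probe set of the opposite sign. Pericellular proteases and their inhibitors had 8 higher and 3 lower of 30 (camera adjusted p = 0.0987, 13 past when adjusted over the list alone). The inhibitors CST6, CSTA and TIMP1 were higher by 2.23, 1.95 and 1.38, and the protease CTSV differed by -1.14. Without the 12 h arrays 5 were higher and 3 lower, without the Smad4-positive 20 min array alone 5 and 3, and without the 4 h arrays 8 and 6. Extracellular matrix genes had 4 higher and 1 lower of 21 (camera adjusted p = 0.09, adjusted p = 0.0333 with the mean of a gene's probe sets, 5 past when adjusted over the list alone). Next to FN1, LAMB3 and COL4A2, chains of laminin and collagen, were higher by 1.23 and 1.09. Of 8 integrins, 0 passed by limma, with 3 at an unadjusted p under 0.05, 0 past when adjusted over the list alone and a camera adjusted p = 0.411. ITGA3, ITGB5, ITGA5 and ITGA6 differed by 0.45, 0.34, 1.02 and -0.14 without passing, and 1 other probe set of ITGA6 had the opposite sign. Without the 4 h arrays 1 integrin was higher.

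Genes of epithelial adhesion and keratins had 9 higher and 1 lower of 28, with 12 past when adjusted over the list alone (limma camera adjusted p = 0.0268, adjusted p = 0.257 with an estimated correlation, adjusted p = 0.0685 and 0.0653 without the Smad4-negative and Smad4-positive 1 h array). The basal keratins KRT16 and KRT14 were higher by 2.58 and 1.23 log2 units and DSP, the gene of desmoplakin, by 0.88, while CLDN3 differed by -0.70. Of 10 mesenchymal markers, 3 were higher and 0 lower, and 3 passed when adjusted over the list alone (camera adjusted p = 0.12, towards higher, although the list's median was -0.04). S100A4 was higher by 1.46, the actin-binding TAGLN by 0.82, and FN1 as given above. VIM differed by 0.85 without passing (limma adjusted p = 0.0975).

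The largest group was the cell cycle, with 25 lower and 2 higher of 58 genes, and 34 past when adjusted over the list alone (limma camera adjusted p = 5.27e-09, adjusted p = 0.257 with an estimated correlation). Without the 1 h arrays 16 were lower and 2 higher. The mitotic kinesins KIF2C and KIF11 differed by -1.23 and -1.07 log2 units and CDC20, an activator of the anaphase-promoting complex, by -1.06. CCNE1, the gene of cyclin E, was higher by 1.06. Cell-cycle inhibitors and p53 targets had 4 higher and 0 lower of 14, with 4 past when adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.257 with an estimated correlation). These were CDKN1A, TP53I3 at 0.76, the stress gene GADD45A at 0.75 and the death receptor TNFRSF10B at 0.74, and 1 was higher without the 20 min or without the untreated arrays and 2 without the 4 h or the 12 h arrays. Apoptosis regulators had 2 higher and 2 lower of 28, with 4 past when adjusted over the list alone (camera adjusted p = 0.358). The adaptor TRADD differed by -1.65 and BIRC5, the gene of survivin, by -0.53 (1 other probe set of the opposite sign), while CASP4, an inflammatory caspase, was higher by 0.93. Without the untreated, the 20 min or the 4 h arrays this group had 1 higher and 1 lower.

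NF-kB targets and chemokines had 7 higher and 2 lower of 22, and 10 passed when adjusted over the list alone (limma camera adjusted p = 0.0132, adjusted p = 0.257 with an estimated correlation). The cytokines CXCL8 and IL6 were higher by 2.53 and 2.11 log2 units and TNFAIP3, a feedback inhibitor of NF-kB, by 1.36. S100 and calcium-binding genes had 6 higher and 2 lower of 20, and 11 past when adjusted over the list alone (camera adjusted p = 0.0065, adjusted p = 0.257 with an estimated correlation). S100P, S100A3 and CALB2 were higher by 2.46, 2.45 and 2.39. In the EGFR family and its ligands and targets, 3 of 13 were higher and 1 lower (camera adjusted p = 0.388, 5 past when adjusted over the list alone). EGFR itself was higher by 1.34, ETV4 by 1.08 and SPRY2 by 0.68, while SPRY1, an inhibitor of receptor signalling, differed by -1.58. Without the untreated, the 1 h or the 12 h arrays 1 member was higher and 1 lower. Interferon-response genes had 2 higher and 4 lower of 34 (camera adjusted p = 0.546, 9 past when adjusted over the list alone). IFITM1, BST2 and LGALS3BP differed by -1.38, -1.58 and -0.51, and ISG20 was higher by 1.17. Without the 20 min or without the 1 h arrays 0 were higher and 3 lower, without the untreated arrays 0 and 4, without the 12 h arrays 1 was higher and 2 lower, and without the 4 h arrays 5 and 3. MHC class II genes had 0 higher and 1 lower of 6, HLA-DMA at -0.64 (camera adjusted p = 0.371, 1 past when adjusted over the list alone), a call that was absent without the 20 min, the 1 h or the 12 h arrays.

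Heat shock and unfolded protein response genes had 7 higher and 1 lower of 24 (limma camera adjusted p = 0.09, 8 past when adjusted over the list alone), and 8 higher and 3 lower without the 4 h arrays. The stress-induced DDIT4, HSPB1 and DDIT3 were higher by 1.76, 1.72 and 1.54 log2 units, and the chaperone HSPA4 by 0.95. Hypoxia and glycolysis genes had 3 higher and 2 lower of 24 (camera adjusted p = 0.0866, 5 past when adjusted over the list alone). P4HA2, a collagen prolyl hydroxylase, and the glycolytic PFKP were higher by 2.32 and 1.18, while PGK1 and PFKL differed by -0.66 and -0.58, and 2 were higher and 1 lower without the untreated arrays. Cholesterol synthesis genes had 1 higher and 5 lower of 20, with 8 past when adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.257 with an estimated correlation). NSDHL, FADS2 and FASN differed by -1.36, -1.72 and -0.43, and EBP was higher by 0.95. Without the 1 h or the 12 h arrays 2 of these were lower, and without the untreated or the 20 min arrays 3. Ribosomal protein genes had 2 higher and 0 lower of 38, RPS14 at 0.72 and RPS23 at 0.70, both on chromosome 5 or X, with 2 past when adjusted over the list alone (camera adjusted p = 0.0493, adjusted p = 0.67 with an estimated correlation, adjusted p = 0.606 after quantile normalization). Without the 4 h arrays 14 were higher, and without any other single array the list had an adjusted p between 0.0847 and 0.23. Proteasome genes had 1 higher and 0 lower of 26, PSMB1 at 0.74, with 1 past when adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.457 with an estimated correlation), and 4 higher without the 4 h arrays, while the list had an adjusted p = 0.0658 and 0.0621 without the Smad4-negative and Smad4-positive 12 h array and 0.0526 without the Smad4-negative 20 min array. Oxidative phosphorylation genes had 4 higher and 4 lower of 41, among them NDUFS4 at 1.03 and NDUFA1 at -0.84 (camera adjusted p = 0.282, 10 past when adjusted over the list alone), with 1 higher and 3 lower without the 20 min or the 12 h arrays, 1 higher and 4 lower without the untreated arrays and 8 higher and 3 lower without the 4 h arrays.

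Markers of other cell types gave no common direction. Of 8 leukocyte markers, CD22 was higher by 1.07 log2 units and CD14 differed by -0.85 (limma camera adjusted p = 0.533, 2 past when adjusted over the list alone). Without the untreated, the 1 h or the 12 h arrays 1 of these markers was higher and 0 were lower. Of 3 endothelial markers, KDR differed by -1.24 and was lost without the untreated, 20 min, 4 h or 12 h arrays, with 1 past when adjusted over the list alone. Of 4 fibroblast markers, 0 passed by limma, with 1 at an unadjusted p under 0.05 and 0 past when adjusted over the list alone.

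**Figure D1:**
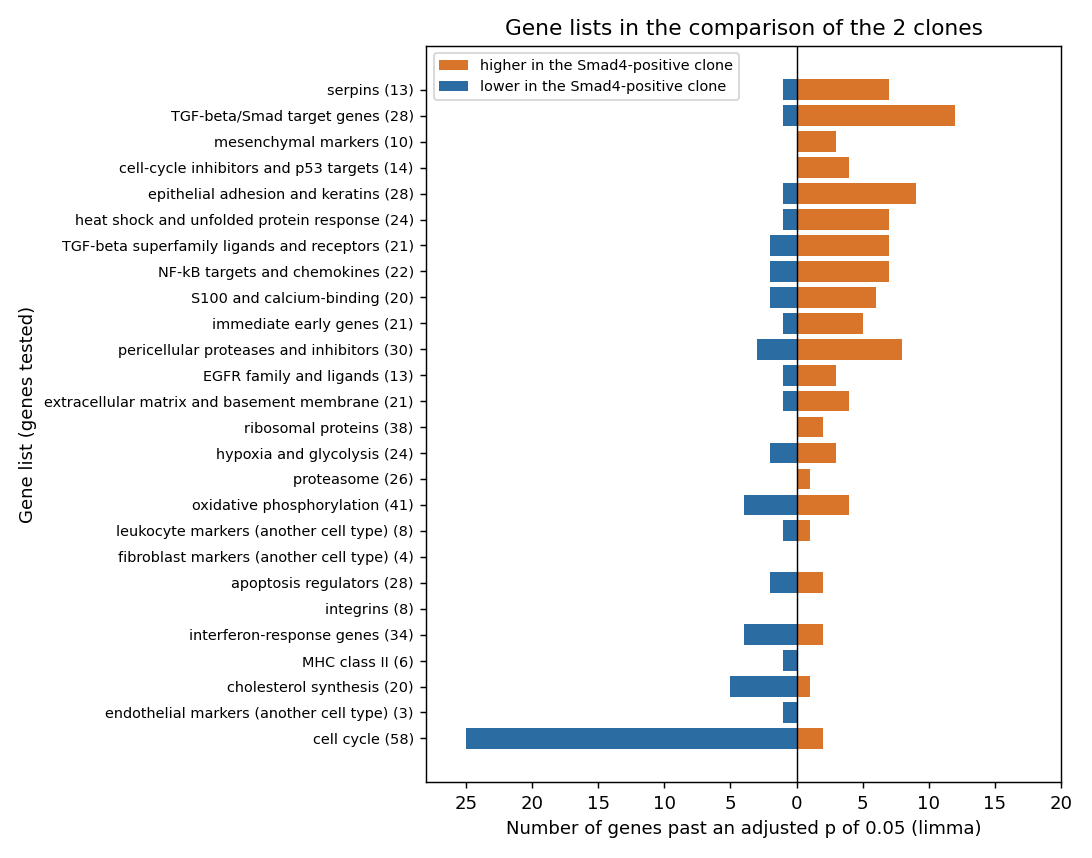
Number of genes of each list past an adjusted p of 0.05 in the clone difference (limma), lower in the Smad4-positive clone to the left and higher to the right, with the number of genes tested in brackets. The cell cycle list has 25 lower and 2 higher genes, and the TGF-β/Smad target list 12 higher and 1 lower.

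Of the 1165 probe sets, 415 differed at least 2-fold and 93 at least 4-fold, 1091 had the same sign at all 5 times, and 2136 had an unadjusted p under 0.05 against 371 expected by chance. They stood for 870 genes. With the array run as a block, which cannot move the clone difference itself, 1155 probe sets passed. Over the 5405 tested genes the clone difference in run A correlated with that in run B at 0.577. The count was 769 without the Smad4-negative 20 min array and 613 with no filter on dim probe sets. As each Smad4 state was 1 clone, differences between the clones from any other source are included.

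The second comparison asked which genes changed with time under TGF-β in the Smad4-positive clone. The TGF-β/Smad target genes rose as a list, with 23 of 28 members at a positive slope and a median of 0.13 log2 units per doubling of (1 + hours) (limma camera adjusted p = 0.00715). This had an adjusted p = 0.387 with an estimated correlation and an adjusted p = 0.657 with the array run as a block, and 0 of the 28 members passed by themselves (4 at an unadjusted p under 0.05, 0 past when adjusted over the list alone). The list test takes no account of the direction in which TGF-β is known to move each member. Among its members, slopes were 0.31 for TGFBI, 0.30 for KLF10, 0.25 for SMAD7, 0.22 for JUNB and 0.23 for MYC, a driver of growth, of which 1 other probe set had the opposite sign. CDKN1A, ID1 and ID3 had slopes of 0.00, -0.07 (1 other probe set of ID1 had the opposite sign) and -0.03, and FOS, EGR1 and SERPINB5, named beforehand as well, 0.07 (2 other probe sets of FOS had the opposite sign), -0.25 and 0.24. PI3, which encodes the protease inhibitor elafin, was the only probe set of 7416 past the threshold, and it fell from a signal of 20802 to 5618 at 12 h (slope -0.53, SE 0.06, limma adjusted p = 0.0101).

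Matrix genes also rose as a list in the Smad4-positive clone (limma camera adjusted p = 0.00261, adjusted p = 0.206 with an estimated correlation), with slopes of 0.35 for TNC, 0.28 for BGN and 0.27 for AGRN. Integrins (adjusted p = 0.0125, adjusted p = 0.373 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 0.0045, adjusted p = 0.308 with an estimated correlation) rose as lists by the same test, with ITGA5 at 0.79 and SREBF2, a regulator of sterol genes, at 0.26. The list of S100 genes fell (adjusted p = 0.00363, adjusted p = 0.308 with an estimated correlation, 5 members past when adjusted over the list alone), with S100A8, S100A7 and S100A9 at -0.29, -0.28 and -0.21. Interferon-response genes fell as a list (adjusted p = 0.0073, adjusted p = 0.308 with an estimated correlation), with IFI35 at -0.43 (1 other probe set of the opposite sign). Ribosomal protein genes fell in all 38 members by sign (camera adjusted p = 6.65e-27, adjusted p = 0.308 with an estimated correlation, 23 members past when adjusted over the list alone), with RPS21 at -0.50 and RPS18 at -0.32. After quantile normalization this list had a camera adjusted p = 0.00552, but its median slope was -0.032 against -0.192 before, with 27 of 38 members below 0. Oxidative phosphorylation genes fell as a list (adjusted p = 0.0045, adjusted p = 0.659 with an estimated correlation), with COX6B1 at -0.38, but had an adjusted p = 0.219 after quantile normalization. No single gene named in these lists passed by itself over all genes, and neither did CYP1A1 (1.09), EDN3 (0.81), TP53BP2 (0.41), HYOU1 (0.31), TAGLN (0.48), TUBB (-0.67), TRADD (-0.60) or RPL7 (-0.30), the next genes by moderated t.

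Of 7416 probe sets, 637 had an unadjusted p under 0.05 in this slope against 371 expected by chance. Late times were confounded with run B, and with the array run as a block 0 probe sets passed and, of these 8 lists, only cholesterol synthesis did (adjusted p = 0.00224), while integrins and oxidative phosphorylation genes turned in direction (adjusted p = 0.738 and 0.527). The block was shared by both clones, so these slopes also draw on the Smad4-negative arrays. On a scale of hours the TGF-β/Smad target genes, integrins and oxidative phosphorylation genes did not pass (adjusted p = 0.0692, 0.0692 and 0.213). The lists also leaned on the Smad4-positive untreated array, the one with the ACTB ratio of 2.63: without it only 1 list passed, the ribosomal proteins, the TGF-β/Smad target genes had an adjusted p = 0.675, and PI3 did not pass, as it did not without the Smad4-positive 20 min or 12 h array, while integrins had an adjusted p = 0.0514 without the 20 min array of this clone and oxidative phosphorylation genes 0.0535 without its 4 h array.

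The third comparison asked the same of the Smad4-negative clone. CYP1A1, an enzyme that oxidises foreign compounds, rose most, from a signal of 317.7 to 8827 at 12 h (slope 1.58, SE 0.23, limma adjusted p = 0.0249), and all 3 of its probe sets passed. SPRR2D, a cornified envelope gene, and SLC7A5, a transporter of large amino acids, rose with slopes of 0.83 and 0.48 (both adjusted p = 0.0483). SERPINA3 fell with a slope of -0.54 (adjusted p = 0.0499) and OLFM4, a secreted glycoprotein, with -0.49 (adjusted p = 0.0469). The TGF-β/Smad target genes had a median slope of -0.03 and did not pass as a list (limma camera adjusted p = 0.822). Of the genes named beforehand none passed, with slopes of -0.27 for TGFBI, -0.15 for KLF10, 0.15 for SMAD7, -0.11 for JUNB, 0.13 for MYC (3 other probe sets had the opposite sign), -0.09 for CDKN1A, 0.12 for ID1, -0.28 for ID3, -0.49 for FOS, -0.01 for EGR1 and 0.16 for SERPINB5.

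RPL37A and SFI1 also fell, with slopes of -0.44 and -0.93 (both limma adjusted p = 0.0483; 1 other probe set of SFI1 had the opposite sign), and so did 1 probe set without a symbol. RAP1A (0.41), CPNE1 (0.49), STC2 (0.58) and EIF4H (-0.36) did not pass. In total 10 probe sets passed, 5 rising and 5 falling, for 7 genes, and 595 had an unadjusted p under 0.05. The directions depended on the scale of time, with 11 rising and 0 falling for late minus early, 3 and 0 on the rank of time and 0 and 3 on hours. As lists, cell cycle genes fell (camera adjusted p = 7.94e-04, adjusted p = 0.681 with an estimated correlation), with FEN1, a DNA repair nuclease, at -0.21, the mitotic kinase AURKA at -0.20 and the replication gene MCM6 at -0.14. Ribosomal protein genes fell (adjusted p = 1.31e-09, adjusted p = 0.681 with an estimated correlation), with RPL38 at -0.34, but had an adjusted p = 0.62 after quantile normalization. Cholesterol synthesis genes rose (adjusted p = 0.0434, adjusted p = 0.681 with an estimated correlation, adjusted p = 0.0533 with the mean of a gene's probe sets), with MSMO1 at 0.31.

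With the array run as a block 0 probe sets passed in this clone, and the ribosomal list had an adjusted p = 0.611 with the direction turned. The block was shared by both clones, so this turn also draws on the Smad4-positive arrays. Within the runs of this clone the ribosomal median fell, by -0.17 from untreated to 20 min and by -0.28 from 4 h to 12 h. The count of 10 was 3, 0, 4 and 5 without the Smad4-negative untreated, 20 min, 1 h and 12 h array, 4, 0 and 6 without the Smad4-positive untreated, 20 min and 1 h array, and the cell cycle and cholesterol lists did not pass without the Smad4-negative 12 h array (adjusted p = 0.15 and 0.577, with 0.0513 for the ribosomal list) or the Smad4-negative untreated array (adjusted p = 0.0581 for both), nor the cholesterol list without the Smad4-negative 1 h array (adjusted p = 0.105) or the Smad4-positive 20 min or 1 h array (adjusted p = 0.053 and 0.0587).

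The fourth comparison tested whether the time course differed between the clones, which is the Smad4 dependence of the response as far as a pair of clones can show it. As a list, the TGF-β/Smad target genes rose more in the Smad4-positive clone, with a median difference of slopes of 0.10 and 19 of 28 members above 0 (limma camera adjusted p = 0.0221, adjusted p = 0.863 with an estimated correlation). The difference of slopes was 0.57 for TGFBI, 0.44 for KLF10, 0.37 for PDGFB, a growth factor of mesenchymal cells, and 0.32 for JUNB, none of them past the threshold, and the other probe set of KLF10 had 0.14. For the other genes named beforehand the differences were smaller or went the other way, with 0.25 for ID3, 0.10 for SMAD7, CDKN1A and MYC, 0.08 for SERPINB5, -0.19 for ID1 and -0.24 for EGR1, apart from FOS at 0.56. The other probe sets of FOS had 0.26 and 0.28, those of MYC 0.17, 0.44 and 0.21, and that of JUNB 0.58. Interferon-response genes went the other way, with a median of -0.11 (adjusted p = 0.014, adjusted p = 0.863 with an estimated correlation) and differences of -0.32 for ISG15, -0.35 for IFI35 and -1.06 for IFI6. Ribosomal protein genes had a median of -0.07 (adjusted p = 1.67e-04, adjusted p = 0.863 with an estimated correlation), with RPL7 at -0.36. After quantile normalization the TGF-β/Smad target list kept an adjusted p = 0.0127, while the interferon and ribosomal lists had adjusted p = 0.0612 and 0.208.

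By limma 0 of 7416 probe sets passed for the difference of slopes, with 231 at an unadjusted p under 0.05 against 371 expected by chance and a smallest adjusted p of 0.185. The next genes by moderated t were TP53BP2 (0.45), CST6 (0.43), ACAA2 (0.38), RSL1D1 (0.37), PI4KB (0.49) and AXIN1 (0.70) on the positive side, and CRYAB (-0.46), SPRR2D (-0.86), TRADD (-0.56), NFIX (-0.89), S100A7 (-0.33) and SRPX (-0.90) on the negative side. Of TP53BP2, RSL1D1 and NFIX, 1, 1 and 2 other probe sets had the opposite sign. The TGF-β/Smad target list did not pass without the Smad4-positive untreated array (adjusted p = 0.869), the Smad4-positive 4 h array (adjusted p = 0.0747) or the Smad4-negative 12 h array (adjusted p = 0.547), and none of the 3 lists passed on a scale of hours (adjusted p = 0.0756, 0.0561 and 0.207), while with the array run as a block the first had an adjusted p = 0.00885. That block leaves every difference of slopes as it was, so this p is no check of the run. The interferon list did not pass without the Smad4-positive 4 h array (adjusted p = 0.0747) or the Smad4-negative 12 h array (adjusted p = 0.0983), nor the ribosomal list without the Smad4-positive 4 h array (adjusted p = 0.0747).

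**Figure D2:**
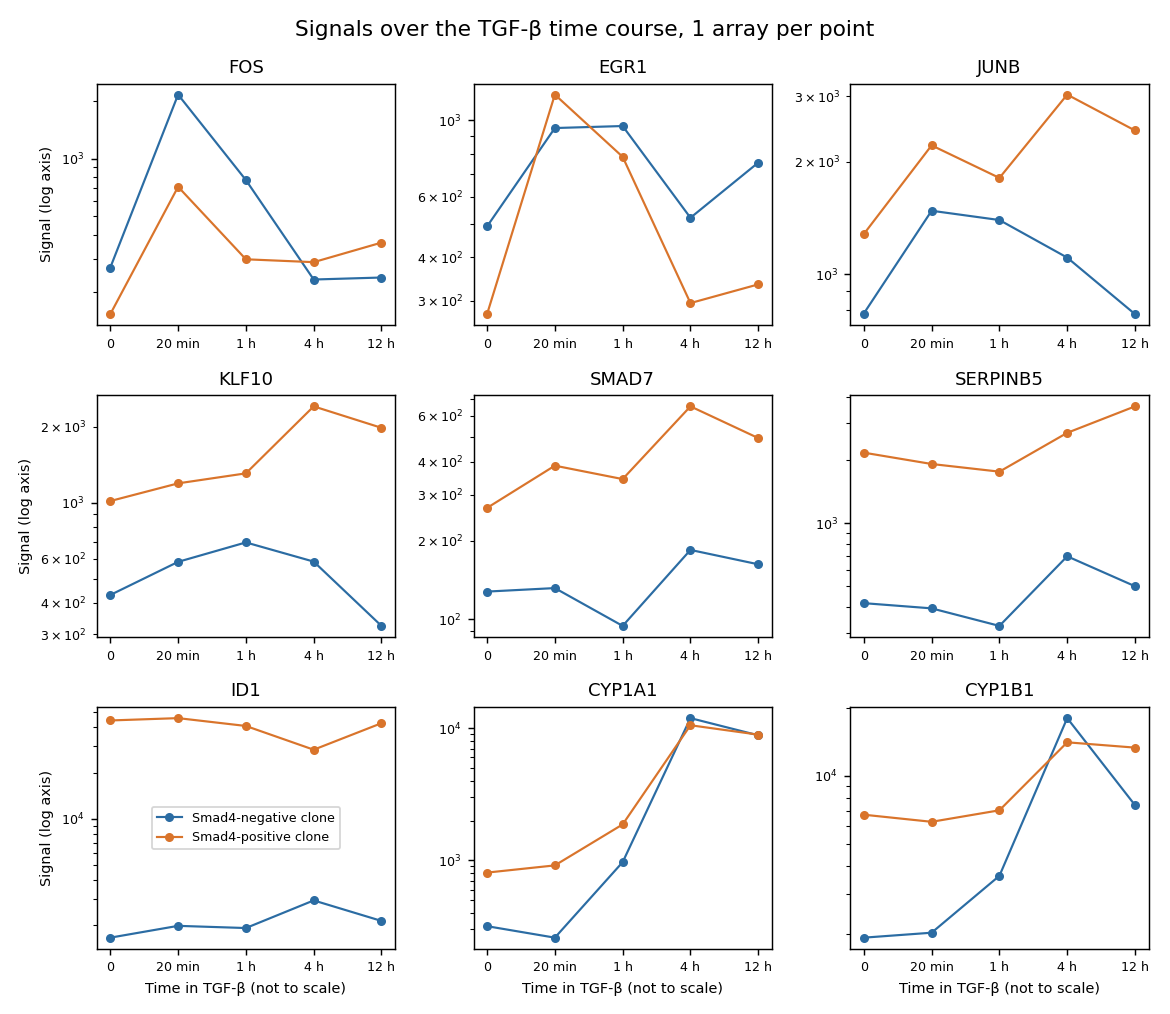
Signals of 9 genes over the time course on a log axis, with 1 array per point and 1 line per clone, each gene by its brightest probe set. FOS peaks at 20 min in both clones (2164 and 713.3), CYP1A1 is high at 4 h and 12 h in both, and ID1 lies far higher in the Smad4-positive clone at every time.

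The fifth comparison followed the early response within each clone, with 1 array against 1 and no test. Immediate early genes, the first genes a stimulus switches on, stood above the untreated array in both clones at 20 min and 1 h. Their median log2 difference was 0.67 at 20 min and 1.35 at 1 h in the Smad4-negative clone, and 0.36 and 0.90 in the Smad4-positive clone, each above at least 99.4% of 10000 random lists. FOS went from 269.7 to 2164 at 20 min in the Smad4-negative clone (8.02-fold) and from 153.9 to 713.3 in the Smad4-positive clone (4.63-fold). Its other 2 probe sets were 15.9-fold (from a signal at the floor) and 19.3-fold higher in the Smad4-negative and 3.3-fold and 2.9-fold in the Smad4-positive clone. EGR1 was 4.33-fold higher at 20 min in the Smad4-positive clone and 1.93-fold in the Smad4-negative clone, and FOSB was 9.29-fold higher in the Smad4-negative clone. Neither clone had an array without TGF-β at 20 min or 1 h, so TGF-β and handling could not be told apart here. The Smad4-positive 20 min array was also the one with the logged fluidics error.

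TGF-β/Smad target genes in the Smad4-positive clone had median differences of 0.42, 0.37, 0.73 and 0.64 log2 units at 20 min, 1 h, 4 h and 12 h, each above at least 99.8% of random lists, and 11 of 28 members were at least 2-fold higher at 4 h. In the Smad4-negative clone the medians were 0.23, 0.26, 0.24 and 0.07, with percentiles of 99.7, 99.8, 98.0 and 73.0, and 2 members were at least 2-fold higher at 4 h. At 1 h the counts went the other way, with 4 members in the Smad4-positive and 5 in the Smad4-negative clone. At 4 h in the Smad4-positive clone SMAD7 was 2.45-fold, KLF10 2.38-fold and JUNB 2.37-fold higher. The values for SMAD7, KLF10 and JUNB in the Smad4-negative clone at that time were 1.44-fold, 1.36-fold and 1.41-fold, and 1 other probe set of JUNB had the opposite sign there, while the other probe set of KLF10 was 1.69-fold and 1.5-fold higher in the Smad4-positive and Smad4-negative clone. SERPINB5 was 1.66-fold higher at 12 h in the Smad4-positive clone and 1.2-fold in the Smad4-negative clone, while its other probe set was 1.98-fold and 2.39-fold higher. NF-kB targets and chemokines stood above at least 99.7% of random lists at 1 h, 4 h and 12 h in both clones, with medians of 0.67, 0.89 and 0.43 in the Smad4-negative clone and 0.45, 0.46 and 0.51 in the Smad4-positive clone. Oxidative phosphorylation genes in the Smad4-positive clone lay below its untreated array at every time, by medians of -0.46, -0.30, -0.54 and -0.30, against -0.04, 0.01, -0.10 and -0.01 in the Smad4-negative clone. For ribosomal protein genes the medians were -0.21, -0.09, -0.89 and -0.60 in the Smad4-positive and -0.17, 0.01, -0.17 and -0.44 in the Smad4-negative clone. DUSP1, a phosphatase that switches off MAP kinases, was 8.41-fold higher at 20 min and 9.04-fold at 4 h in the Smad4-positive clone. Its untreated signal there was 72.5, near the floor. NR4A1, a nuclear receptor of the early response, was at least 11.6-fold higher at 1 h in the Smad4-negative clone from a signal at the floor.

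At least 2-fold differences were counted for 689, 840, 808 and 731 probe sets at the 4 times in the Smad4-negative clone and for 962, 1137, 1041 and 897 in the Smad4-positive clone. Every value in the Smad4-positive clone rests on its untreated array with the ACTB ratio of 2.63, and no replicate tells array noise from change.

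The last comparison asked which genes moved at the same time in both clones, each time against the untreated arrays. CYP1A1 rose over both clones, by 4.47 log2 units at 4 h (SE 0.40, limma adjusted p = 4.39e-04) and by 4.13 at 12 h (SE 0.40, limma adjusted p = 9.91e-04), and all 3 of its probe sets passed at both times. In the Smad4-negative clone it was 37.5-fold and in the Smad4-positive clone 13-fold higher at 4 h. WNT5A, a secreted signal of the non-canonical Wnt pathway, rose by 1.92 at 4 h (adjusted p = 0.0237). KDM4B, a histone demethylase, fell by 3.03 at 4 h (adjusted p = 0.0117), CHKA, a choline kinase, fell by 2.36 at 12 h (adjusted p = 0.0274), and COX6B1, a subunit of cytochrome oxidase, fell by 1.44 at 4 h and 1.26 at 12 h (adjusted p = 0.00899 and 0.0274). Of the genes named beforehand none passed at any time. At 4 h they differed by 0.96 for MYC and 0.09 for ID1 (1 other probe set of each had the opposite sign), 0.91 for SMAD7, 0.87 for JUNB, 0.84 for KLF10, 0.53 for SERPINB5, 0.35 for FOS, 0.29 for CDKN1A, 0.09 for EGR1, -0.35 for ID3 and -0.40 for TGFBI, and at 20 min FOS and EGR1 differed by 2.61 and 1.53 (adjusted p = 0.367 and 0.388). TGFBI was not a shared fall at 4 h: it differed by 0.78 in the Smad4-positive clone and by -1.57, down to the floor, in the Smad4-negative clone.

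At 4 h 7 probe sets passed, 4 higher and 3 lower, and at 12 h 5 passed, 3 higher and 2 lower, with 884 and 873 at an unadjusted p under 0.05. By limma 0 passed at 20 min and 0 at 1 h, with 672 and 729 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.278 and 0.0887; without the Smad4-negative untreated array 1 passed at 20 min, and at 1 h 2 passed without the Smad4-negative 1 h array and 1 without either 12 h array. The 4 h and 12 h arrays were all in run B and the untreated arrays in run A, so time and run could not be told apart in these contrasts. The count at 4 h was 56 without the Smad4-negative 4 h array and 3 without the Smad4-positive untreated array, and the count at 12 h was 70 and 74 without the Smad4-negative and Smad4-positive 4 h arrays and 3 without either untreated array, either 20 min array or the Smad4-negative 12 h array.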

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

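The tests of the array run and of brightness for the ribosomal genes, and of the array run for CYP1A1 and CYP1B1, were chosen only after those results were seen.

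The time course differed between the clones for 3 lists by a direct test of the difference of slopes, as the report gives with limma's camera, but all 3 had an adjusted p = 0.863 with an estimated correlation, and after quantile normalization the interferon and ribosomal lists had adjusted p = 0.0612 and 0.208. The median difference of slopes, Smad4-positive minus Smad4-negative, was 0.098 log2 units per doubling of (1 + hours) for TGF-β/Smad target genes, -0.113 for interferon-response genes and -0.072 for ribosomal protein genes. CRYAB, a small heat shock protein gene, and RSL1D1, a nucleolar protein gene, each moved 1 way on all 4 treated arrays of 1 clone and the other way on all 4 of the other. Their differences of slopes were -0.46 and 0.37 (limma adjusted p = 0.999 for both), and the opposite movement itself was not tested. Among 77 genes examined 2 did this, and 280 of all 5405 tested genes did, so the movement was no more common among the genes examined, and the 4 differences of a clone share its 1 untreated array.

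For the number of probe sets that differed between the clones, the real split of the arrays stood apart from the other splits drawn. Of 126 possible splits of the 10 arrays into 5 and 5, 100 were drawn, and only 1, the real one, gave as many as 1165, with 1 as the highest of the others. The highest of the others among the 9 drawn splits that part the arrays of every time was 0. The other splits hold the clone difference in their spread, which keeps their counts low. The arrays of a clone are also not known to be separate cultures. The splits thus show that arrays of the same clone resemble each other, and no more. For the difference of slopes the real count was 0, so that all 100 splits had to give as many, and this says nothing about chance. The highest other gave 629. That split set the early Smad4-negative and late Smad4-positive arrays apart from the rest, so it points to a structure of the samples, namely the difference between the clones.

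Ribosomal protein transcripts, which are among the brightest on these arrays, had median slopes of -0.192 and -0.115 in the Smad4-positive and Smad4-negative clone, with 38 and 31 of 38 members below 0 and 0 of these past the threshold by themselves in either clone, while RPL37A, which was not on the list, passed in the Smad4-negative clone. With an estimated correlation the list had an adjusted p = 0.308 and 0.681 (limma camera). After quantile normalization, which removes differences between arrays that depend on brightness, the medians were -0.032 and -0.015, and 117 other genes matched on brightness had deposited medians of -0.071 and -0.051. The matched genes had medians of 0.058 and 0.028 after quantile normalization, so the ribosomal genes lay below equally bright genes before and after it, and at the preset correlation the list had an adjusted p = 0.00552 and 0.62 after it. The interquartile range of the ribosomal slopes, -0.239 to -0.16 and -0.155 to -0.041, overlapped that of the matched genes, -0.18 to -0.006 and -0.12 to 0.014, so how much of the fall came from brightness stays open. With the array run as a block the medians were -0.101 in the Smad4-positive clone, with 26 of 38 members below 0, and 0.014 in the Smad4-negative clone. The block was shared by the clones, so these are not the slopes of either clone within its own runs. Within the runs, where 1 array was set against 1, the median changed by -0.17 from untreated to 20 min and by -0.28 from 4 h to 12 h in the Smad4-negative clone, which goes against the runs as the whole source there, and by -0.21 and 0.27 in the Smad4-positive clone. In the Smad4-positive clone run and time cannot be told apart because early and late arrays sat in different runs, and in the Smad4-negative clone the runs stay open as part of the source. A response to TGF-β, or to time in culture, stays open and untested.

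CYP1A1 and CYP1B1, classic targets of the aryl hydrocarbon receptor, were higher late (4 h and 12 h) than early (untreated and 20 min) on all 5 probe sets in both clones, by 2.39 to 5.26 log2 units in the Smad4-negative and 1.08 to 3.54 in the Smad4-positive clone. Within a single run, 0 of the 5 probe sets rose by over 1 log2 unit in both clones, so the array runs cannot be told apart from time as the source. The 1 h arrays, whose run is not known, had CYP1A1 already higher by 0.72 to 1.83. In both clones its values at 1 h lay outside the range of the early arrays and outside that of the late arrays. The 1 h arrays may belong to neither run, which leaves run and time both open. CYP1B1 was higher at 1 h by 0.91 and 0.95 in the Smad4-negative clone, but differed by only 0.06 and -0.08 in the Smad4-positive clone. From 4 h to 12 h, within run B, CYP1B1 differed by -1.28 and -1.53 in the Smad4-negative and by -0.08 and -0.13 in the Smad4-positive clone. A wider response of genes regulated by the aryl hydrocarbon receptor cannot be told apart from none either, since only 5 of 10 other such genes were tested and they went both ways, with medians of 0.37 and 0.56 in the Smad4-negative and Smad4-positive clone, TIPARP at 0.37 and 0.74 and NQO1 at -0.20 and -0.55. An effect of TGF-β or of handling at the late times was not tested, since no late untreated arrays were part of the design.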

How the results depend on the processing

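Chosen only after the data were seen were the slopes without the 1 h arrays, the list counts without single arrays and the list tests under the alternatives other than those of the list test itself. Signal near background limits these tests, and the filter moved the clone count more than any other choice: without a filter on dim probe sets 12559 were tested, and the counts were 613 for the clone difference, 0 for either slope and 0 for the 4 h and 12 h contrasts, with 1 at 20 min and 19 at 1 h; the cause was not tested. The strict filter gave 6 for the Smad4-negative slope, 1 at 1 h and 18 at 12 h. The clone difference otherwise stayed within 1.5 times of 1165 under every alternative run on it except leave-one-out, where it ranged from 769 (without the Smad4-negative 20 min array) to 1287. No named gene reversed its direction while called. SMAD4 is given as -0.24 log2 units, from -0.474 to 0 over the alternatives, but its probe set was below the floor on 9 of 10 arrays, so that the -0.24 rests on the Smad4-negative untreated array.

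The calls on the slopes depended on the settings below, and the cause was not tested. For the Smad4-positive slope, where 1 probe set passed, the counts were 2 after scaling to a common median, 2 for a variance prior without a trend, 0 with the array run as a block, 0 on the rank of time, 0 on hours, 3 for late minus early and 0 without the 1 h arrays. Leave-one-out gave 0 to 5, with 4 and 5 without the Smad4-negative 4 h and 12 h array and 0 without the Smad4-positive untreated, 20 min or 12 h array. For the Smad4-negative slope, where 10 passed, they were 0 for a prior without a trend, 0 with the run as a block, 3 on the rank of time (all rising), 3 on hours (all falling), 11 for late minus early (all rising) and 0 without the 1 h arrays. Leave-one-out gave 0 to 15, with 3, 0, 4 and 5 without the Smad4-negative untreated, 20 min, 1 h and 12 h array and 4, 0 and 6 without the Smad4-positive untreated, 20 min and 1 h array. The difference of slopes stayed at 0 throughout, with leave-one-out from 0 to 0. At 4 h, where 7 passed, and at 12 h, where 5 did, quantile normalization gave 5 and 6, a common median 6 and 4 and the robust prior 7 and 5, while a prior without a trend gave 0 and 0. Leave-one-out gave 0 to 1 at 20 min (1 without the Smad4-negative untreated array), 0 to 2 at 1 h (2 without the Smad4-negative 1 h array, 1 without either 12 h array), 3 to 56 at 4 h (56 without the Smad4-negative 4 h array, 3 without the Smad4-positive untreated array) and 3 to 74 at 12 h (70 and 74 without the Smad4-negative and Smad4-positive 4 h array). The run as a block was not run for the 1 h, 4 h and 12 h contrasts, which it is confounded with.

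Of the lists, 10, 8, 3 and 3 passed camera for the clone difference, the Smad4-positive slope, the Smad4-negative slope and their difference. With an estimated correlation 0 passed in all 4. The Smad4-positive slope had 3 lists with the run as a block and 5 on hours, and the difference of slopes 1 after quantile normalization and 0 on hours. Leave-one-out gave 8 to 10, 1 to 9 (1 without the Smad4-positive untreated array), 1 to 3 (1 without the Smad4-negative 12 h array) and 0 to 7 (0 without the Smad4-positive 4 h array, 7 without the Smad4-positive 12 h array), and the cause was not tested. With the mean of a gene's probe sets the cholesterol list did not pass for the Smad4-negative slope (adjusted p = 0.0533), while extracellular matrix passed for the clone difference (0.0333) and the proteasome for the Smad4-positive slope (0.0435). The list test was not run with the robust prior.

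Counts of 2-fold differences at single times followed the floor and the filter. At 20 min, 1 h, 4 h and 12 h in the Smad4-negative clone they were 354, 489, 529 and 448 with the floor at the 40th percentile, 1368, 1871, 1610 and 1477 without a filter and 97, 107, 159 and 158 with the strict filter. In the Smad4-positive clone they were 632 at 20 min with the higher floor, 1913, 2575, 1758 and 1687 without a filter and 207, 212, 323 and 202 with the strict filter. The filters changed the number of probe sets counted and the higher floor did not.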

Other observations

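The test of neighbouring genes given here was written before its result was seen. Genes that differed between the clones were unevenly spread over the genome. On the X chromosome 113 of 206 tested genes passed the clone test by limma (54.9%), 44 higher and 69 lower in the Smad4-positive clone. On chromosome 5 the count was 67 of 228 (29.4%), with 59 higher and 8 lower, against 690 of 4967 (13.9%) on all chromosomes other than 5 and X. Named genes on the X chromosome include MAGEA10 (at least 17.5-fold higher), NSDHL (-1.36 log2 units), PGK1 (-0.66) and NDUFA1 (-0.84).

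Neighbouring genes, ordered by assembly GRCh38.p14, differed in the same direction. In windows of 25 neighbouring genes, chosen by the search itself after the values were seen, the largest median was -1.17 log2 units, from GLA to THOC2 on the X chromosome, with 24 of 25 genes lower and 21 past the threshold. A window from ELF4 to NSDHL had a median of -1.14, and higher windows were found from TNPO1 to PAM on chromosome 5 (0.82) and from PUDP to RPS6KA3 on the X chromosome (0.77). In all 15 windows without overlap, 8 higher and 7 lower, exceeded the 95th percentile of the largest window in random gene orders (0.44), of which 0 of 10000 reached 1.17 (permutation p = 0.0001, the smallest they can give). The 15 windows lay on chromosomes 1, 5, 8 and X. Adjoining windows were counted apart, so they are not 15 distinct regions.

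A candidate explanation is that the clones carry different copy numbers of chromosome segments, as sublines of a cancer line may come to do, which fits the test (permutation p = 0.0001) but was read from RNA alone, and regulation shared by neighbouring genes stays open. The groups that led the clone difference lay mostly outside chromosomes 5 and X. There, TGF-β/Smad target genes had 11 higher and 1 lower of 27, serpins 7 and 1 of 13, and cell cycle genes 1 higher and 24 lower of 53. Ribosomal protein genes had 0 and 0 of 34 there, oxidative phosphorylation genes 2 and 2 of 35 and hypoxia and glycolysis genes 2 and 1 of 22. Lower windows were also found on chromosomes 1 and 8, such as HDAC1 to ZMPSTE24 (-0.51) and SPIDR to RPL7 (-0.48). Leaving out chromosomes 5 and X therefore cannot set these groups apart from the candidate explanation. Whether members of a list, such as the SERPINB genes, neighbour each other was not examined, so they may not be separate cases.

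Across the 5405 tested genes, which are not independent replicates, the slopes of the clones correlated at 0.328. The clones' differences between 20 min and untreated, within run A, correlated at 0.183, and those between 12 h and 4 h, within run B, at -0.04.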
